A study of Mus musculus with 8 samples.

How the data were processed

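Small RNA libraries (NEBNext Small RNA kit, per the labels' protocols) were sequenced from mouse cells and bone. MC3T3-E1 sc4 is a cloned pre-osteoblast line that was derived from mouse calvaria. Per the series' design text, MC3T3 cells received ascorbic acid and β-glycerol phosphate, and equal amounts of RNA from 3 cultures were pooled for each of 5 days (0, 6, 10, 17 and 24). The 5 MC3T3 libraries therefore hold 1 library per day. The other 3 libraries came from calvaria, the flat bones of the skull vault (parietal and frontal), of newborn female mice carrying Prrx1-Cre, after a brief collagenase and trypsin digestion. The labels do not say whether the 3 calvaria libraries are separate animals, so p-values measure the spread between these samples.

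The deposited raw table holds estimated counts per mature arm and precursor, and its totals differ between libraries. The deposited normalized table holds RPM, library-scaled read counts, and each value equals the raw value over its library total within 0.013 RPM. Reads were handled with cutadapt 0.9.5 and Bowtie 0.12.7 and the mm10 genome, per the submitters' processing notes, which give the tools no role or order. The quantifier and the miRBase release are not given in the sources used here. The raw table has 1418 entries for 1281 mature miRNAs, and 76 mature miRNAs have several entries, 1 per precursor. Of the nonzero raw values, 82.4% were whole (within 0.005) for miRNAs with 1 entry and 17% for miRNAs with several entries. Counts were therefore divided mostly for the latter, but in part also for miRNAs with 1 entry, which summing over precursors does not undo. miRNAs with several near-identical precursors are uncertain at the level of the single entry. In 2 cases a pair of entries shared both names and stayed separate features. The day in each MC3T3 column name is 3 lower than the day in the matching title, for every library; days follow the titles, and a constant shift leaves the slope as it is. Which of the 2 counts starts with the osteogenic medium is not given in the sources used here. The 4 later column names also carry the mark "veh" and the day 0 name does not; its meaning is not given in the sources used here. All 8 columns were matched to a sample.

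Library totals were 4031962, 3155545, 3104617, 3940372 and 2742368 counts at days 0, 6, 10, 17 and 24, and 1183011, 2023036 and 1343318 counts in the 3 calvaria libraries. Counts of 10 or more were found for 351 to 386 mature miRNAs in the MC3T3 libraries and 392 to 443 in the calvaria libraries. Intervals for single libraries are exact 95% Poisson intervals of the count, and ratios of counts carry exact binomial intervals. A group with 0 counts was given a limit of 3 counts over all 5 MC3T3 libraries together, or 0.177 RPM. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

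Expected counts were rounded to whole numbers. Entries needed 10 counts in at least 2 MC3T3 libraries (day trend) or in at least 3 of the 8 libraries (calvaria against MC3T3). With the latter filter, an entry near absent from 1 material was tested only through its counts in the other. Its direction was then largely fixed by the filter. Both comparisons used the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, Benjamini-Hochberg adjustment over all entries tested and a threshold of 0.05. The day trend was linear over the 5 MC3T3 libraries with 3 residual degrees of freedom, and its log2 change is the fitted slope times 24 days. Its spread is the departure from a straight line on the log scale, so it holds noise and any curved course alike. With 1 library per day no 2 days could be compared with a test. The calvaria comparison set 3 libraries against all 5 MC3T3 libraries, so the MC3T3 spread includes the change over days. A joint fit of material and day over all 8 libraries served the comparison of both sets of changes, with 50 simulated data sets holding no effect beside it.

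Lists were tested on summed counts per mature miRNA, with camera at its preset correlation, camera with an estimated correlation, and fry (limma 3.58.1), on log2 CPM with a prior count of 2. The 22 lists were the miR-101 family, miRNAs reported to promote or to restrain osteoblast differentiation, the miR-29, let-7, miR-34, miR-30 and miR-15/16 families, the miR-17-92 cluster with its paralogs, the clusters of miR-322 with miR-503, miR-199 with miR-214, miR-143 with miR-145, miR-23 with miR-27 and miR-24, and miR-183 with miR-96 and miR-182, the Hox and Dlk1-Dio3 clusters, and markers of cartilage, blood cells, endothelium, striated muscle, nervous system and epithelium. Lists with under 3 measured members were given as values only. Some lists share members: 6 of the 11 miRNAs reported to promote differentiation, 12 of the 19 reported to restrain it and 1 of the 12 blood cell miRNAs also stand in another list. Steps between days were given as ratios, and a list's median step was placed among 10000 random lists of the same size matched on mean expression.

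Designs, lists, alternatives and the rule for named miRNAs were set before the data were examined. The rule took, per comparison, the 10 largest changes in each direction among entries past the threshold with a mean of at least 50 RPM. With fewer than 5 in a direction of the day trend, it added those with the largest ratio of day 24 to day 0 and a course that never turned, named as not past the test. It also took all miR-101 arms, the 5 most abundant miRNAs per material, the 3 most abundant members of each list, and all members that passed where 4 or fewer did. Other miRNAs are named as chosen after their values were seen.

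The alternatives were DESeq2 size factors, library totals or upper quartile factors in place of TMM, the DESeq2 Wald test (DESeq2 1.42.0), limma on the deposited RPM with a pseudocount of 1 or 10, no count filter or a minimum of 100 counts, summed counts per mature miRNA, other day scales, all 8 libraries sharing the spread, other sets of MC3T3 days, and each library left out in turn. On simulated data with known changes, the day trend test (464 entries) recovered 8.33% of 48 entries changed 2-fold, 82% of 50 changed 4-fold, and 100% of 49 changed 8-fold and of 50 changed 16-fold. It called 4 of 267 unchanged entries. These changes were planted in many entries, as straight trends with independent noise, while 14 of 469 real entries passed. Real recovery may therefore be lower where few entries change or courses curve. The calvaria test (536 entries) recovered 52.1% of 48 changed 2-fold and 100% of 49 changed 4-fold, of 49 changed 8-fold and of 50 changed 16-fold, and called 7 of 340 unchanged entries. Precursor positions came from GENCODE M21 on mm10, where 811 of 855 precursors (94.9%) matched 1 annotated gene by name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.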

Results

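Small RNA was profiled in MC3T3-E1 sc4 pre-osteoblasts titled day 0 (undifferentiated) and days 6, 10, 17 and 24 of osteogenic differentiation (1 library per day, each pooled from 3 cultures) and in 3 libraries of newborn mouse calvaria. Values are estimated counts per mature arm and precursor, and the RPM derived from them. Of the mature miRNAs, 351 to 386 had at least 10 counts in an MC3T3 library and 392 to 443 in a calvaria library. No single day had a replicate.

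In calvaria the most abundant miRNAs by mean share were let-7i-5p with 8.11% ± 0.809 of counts (SD, n = 3), miR-21a-5p with 7.43% ± 2.18, miR-140-3p with 7.34% ± 2.32, miR-148a-3p with 6.75% ± 2.18 and miR-143-3p with 5.57% ± 0.739. In MC3T3 cells they were miR-21a-5p with 21.75% ± 13.82 (SD over the 5 days), miR-143-3p with 10.26% ± 1.21, let-7i-5p with 6.5% ± 1.28, miR-99a-5p with 5.54% ± 2.87 and let-7f-5p with 4.61% ± 0.63. The order differed between libraries: miR-140-3p was first in calvaria 1 and 2, miR-21a-5p in calvaria 3 and on all MC3T3 days but day 17, when miR-143-3p was. The day 0 library stood apart from the rest. miR-21a-5p took 45.55% of its counts against 11.23% to 20.14% on later days, and its 10 most abundant miRNAs took 76.63% against 61.83% to 62.43%. Across miRNAs, rank correlations were at most 0.963 between day 0 and any later day and at least 0.979 among days 6 to 24. They were 0.990 between calvaria 1 and 2, 0.974 and 0.978 between these and calvaria 3, and 0.488 to 0.540 between materials. The miRNAs are not independent replicates. The median SD of log2 CPM over the calvaria libraries was 0.30 for 471 miRNAs.

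The series title names miR-101a, so the miR-101 family was measured first in every library. The guide arm miR-101a-3p was higher in RPM at each step of the time course, from 1015 (95% interval 984.5 to 1047) at day 0 to 3608 at day 6, 5832 at day 10, 6528 at day 17 and 7174 (7075 to 7275) at day 24. The ratio of day 24 to day 0 was 7.07 (6.83 to 7.31) in RPM and 5.15 after TMM scaling, and its rank by abundance went from 50 to 27. In calvaria it stood at 4323 ± 573 RPM (SD, n = 3). miR-101b-3p had no such course, with 1931, 3000, 3008, 2673 and 2589 RPM over the 5 days and 2049 ± 180 RPM in calvaria. miR-101c was far scarcer, with 7.69 RPM at day 0, 47.4 at day 24 and 25 ± 1.55 in calvaria. The passenger arms were near absent: miR-101a-5p had 0 to 3 counts per library, and miR-101b-5p had 1 count, at day 6.

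The 3 precursors lie at separate loci of mm10. Mir101a is at chromosome 4, 101346945 to 101347027, minus strand, within an exon of the lincRNA E130102H24Rik. Mir101b is at chromosome 19, 29135279 to 29135375, plus strand, in an intron of Rcl1. Mir101c is at chromosome 9, 3038669 to 3038743, minus strand, outside annotated genes. The precursors of miR-101a and miR-101b share a run of 20 bases, and those of miR-101a and miR-101c a run of 19 bases (ACAGTACTGTGATAACTGA). Fractional counts occur in all 3, such as 11385.5 for miR-101a-3p and 54.5 for miR-101c at day 6, and 2984.5 for miR-101b-3p in calvaria 3. How reads were divided between the members is not given in the sources used here. The values of all 3 are uncertain to that extent, and most so for the scarce miR-101c.

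**Figure D1:**
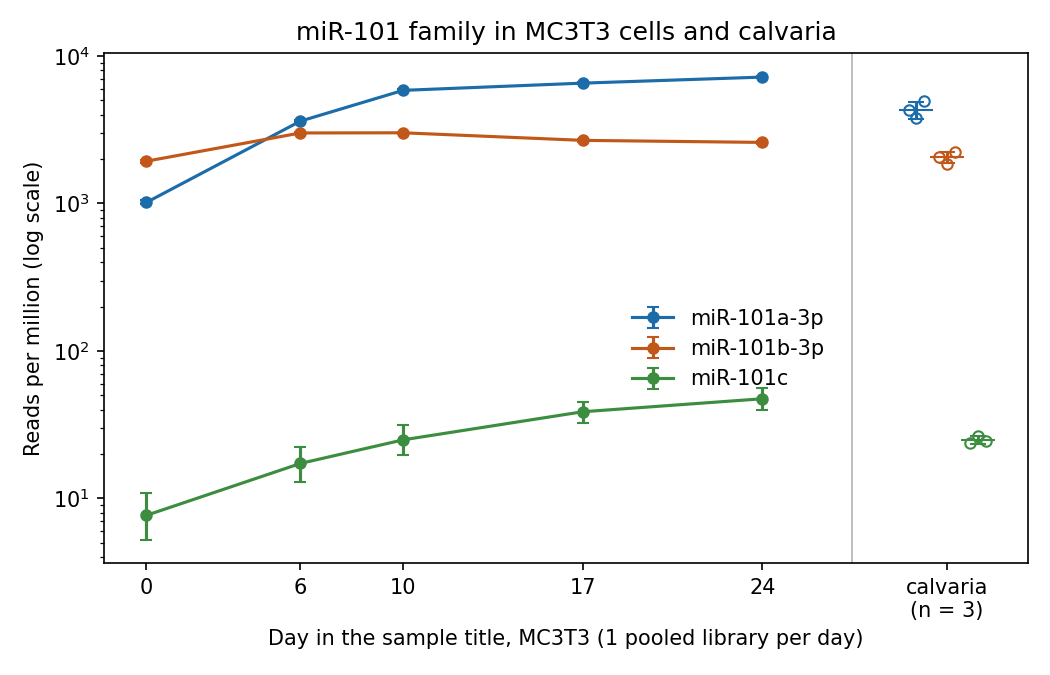
RPM (log axis) of the miR-101 family against the titled day for the 5 MC3T3 libraries (filled points with 95% counting intervals), and in the 3 calvaria libraries (open points with mean ± SD). miR-101a-3p goes from 1015 to 7174 RPM over the days while miR-101b-3p stays between 1931 and 3008 RPM.

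The linear day trend gave miR-101a-3p a fitted 24-day log2 change of 2.26 ± 0.54 (SE) with an adjusted p of 0.0702 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. It therefore missed the threshold of 0.05. Over the other settings its adjusted p ranged from 0.000843 (on a log2 day scale) to 0.125 (without day 6), and it passed without day 0 (log2 1.41, adjusted p = 0.00577), without day 10 (2.37, 0.0412) and without day 24 (3.20, 0.0288). miR-101c rose by 2.30 ± 0.41 (adjusted p = 0.0281), a call lost with library totals (0.0696), with limma and a pseudocount of 1 (0.0526), without day 6 (0.0895), without day 17 (0.055) and without day 24 (0.0551). The miR-101c rise may not be separate from that of miR-101a-3p, since their precursors share a run of 19 bases. miR-101b-3p had 0.00 ± 0.34 (adjusted p = 0.999).

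Which other miRNAs moved with the titled day was asked with the same fit. miR-210-3p, a miRNA induced by hypoxia and reported to promote osteoblast differentiation, rose from 100.2 RPM at day 0 to 3311 at day 17 and 2673 at day 24, a ratio of 26.7 (24.1 to 29.6) between the ends. miR-99a-5p rose from 13160 RPM at day 0 to 80010 at day 24, a ratio of 6.08 (6.02 to 6.14). Both ratios are in RPM, where the large miR-21a-5p share lowers all other day 0 values. TMM scaling makes them smaller, with factors of 0.6944 at day 0 and 0.9534 at day 24. miR-125b-1-3p, a passenger arm, fell from 597.7 to 167.7 RPM. The fitted 24-day log2 changes were 4.93 ± 0.93 (adjusted p = 0.0309), 2.18 ± 0.44 (0.0320) and -2.37 ± 0.47 (0.0320) in the edgeR quasi-likelihood test. Single libraries moved these changes, for miR-210-3p to 3.91 without day 0, 4.34 without day 17 and 6.73 without day 24, for miR-99a-5p to 1.51 without day 0 and 3.06 without day 24, and for miR-125b-1-3p to -3.49 without day 24. All 3 lost the call without day 6 (adjusted p = 0.0895 each) and with a minimum of 100 counts (0.0508 each). Without day 17, miR-99a-5p (0.0576) and miR-125b-1-3p (0.0783) lost it as well, and without day 10 miR-125b-1-3p did (0.0511). miR-125b-1-3p also lost it with library totals (0.0728) and with limma (0.0789 and 0.0733 for pseudocounts of 1 and 10), and miR-99a-5p with summed counts (0.0502).

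Of the steady courses that did not pass the test, miR-195a-5p went from 23.6 to 660.9 RPM (log2 3.58 ± 0.998, adjusted p = 0.0916) and its passenger arm miR-195a-3p from 20.1 to 257.8 RPM (2.66 ± 0.68, 0.0762). In the other direction miR-30c-2-3p went from 334.8 to 102.5 RPM (-1.94 ± 0.54, 0.0907) and miR-30a-5p from 29510 to 14410 RPM (-1.30 ± 0.43, 0.121). Mir210 lies at chromosome 7, 141221384 to 141221493, outside annotated genes. Mir99a lies at chromosome 16, 77598936 to 77599000, in an intron of Mir99ahg.

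Over all 469 entries tested, 6 rose and 8 fell with day at an adjusted p under 0.05 in the edgeR quasi-likelihood test, and 50 and 53 had an unadjusted p under 0.05. The others that passed had means under 50 RPM. Of these, miR-3068-5p, miR-1983, miR-1187, miR-582-3p and miR-92a-1-5p were chosen for naming after their values were seen. miR-146a-5p (3.27), miR-101c, miR-3068-5p (2.15) and miR-499-5p (3.55) rose; miR-196a-5p (-2.97 and -2.50 at its 2 precursors), miR-1983 (-5.02), miR-1187 (-2.97), miR-582-3p (-4.61), miR-92a-1-5p (-2.67) and miR-155-5p (-5.73) fell. The counts depended on single libraries: 35 rose and 40 fell without day 0, 0 and 3 without day 6, 3 and 2 without day 17, and 11 and 16 without day 24. With library totals 6 rose and 5 fell. Summed per mature miRNA, 4 of 391 rose and 5 fell. The median log2 change of all entries was -0.12 with TMM, -0.12 with DESeq2 size factors, 0.11 with library totals and -0.37 with upper quartile factors.

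**Figure D2:**
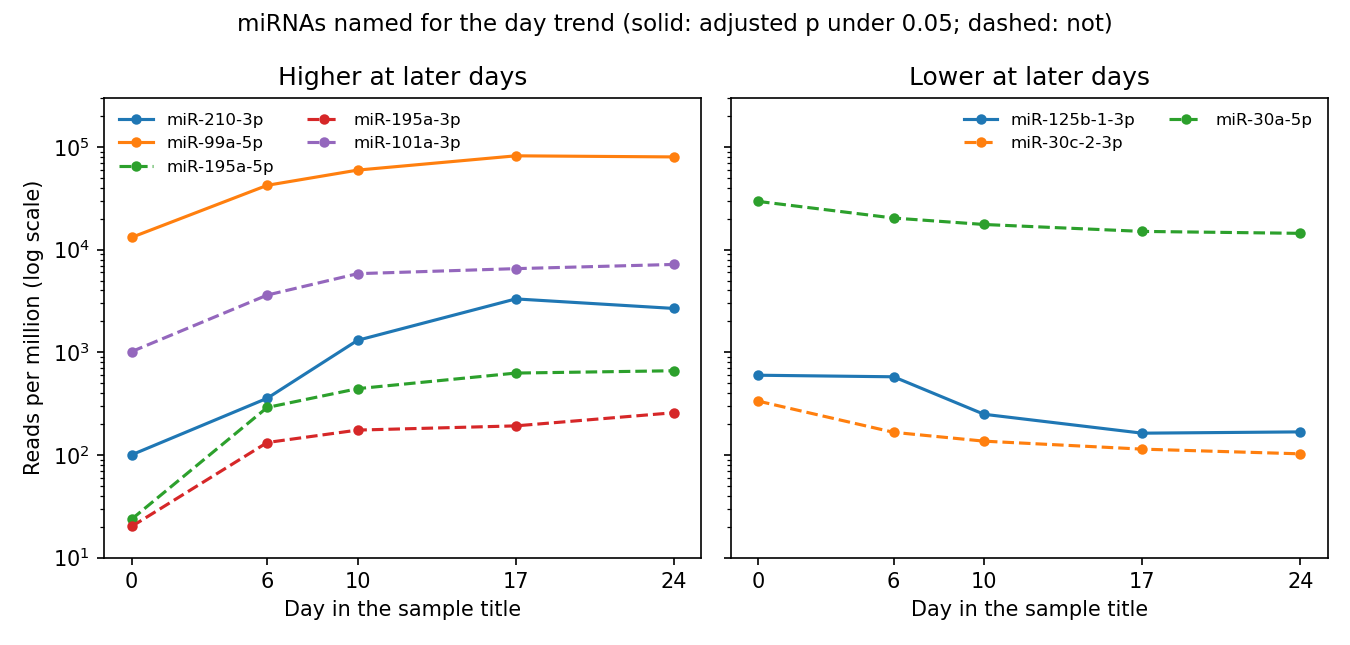
RPM (log axis) against day for the miRNAs named by rule for the day trend, 1 pooled library per point, with solid lines for those past the test and dashed lines for those not. miR-210-3p climbs from 100.2 to 2673 RPM and miR-125b-1-3p drops from 597.7 to 167.7 RPM.

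The largest single step was the first. The SD of log2 ratios over 377 miRNAs was 1.02 from day 0 to day 6, against 0.48 from day 6 to 10, 0.52 from day 10 to 17 and 0.40 from day 17 to 24. From day 6 to day 24 as a whole it was 0.75. By more than 2-fold, 53 miRNAs were higher and 32 lower at day 6 than at day 0, and 29 higher and 26 lower at day 24 than at day 6. As medians of these libraries, with percentiles among random matched lists, the miR-15/16 family stood 1.31 log2 higher at day 6 than at day 0 (99.7th percentile) and the miR-322 and miR-503 cluster 0.90 higher (98.2nd). The Hox cluster was at -0.82 (0.44th). From day 6 to day 24 the miR-29 family, which targets collagen transcripts, stood 0.88 higher (99.9th), the miR-101 family 1.33 higher (98.9th) and the miR-23/27/24 clusters 0.60 higher (96.2nd). The growth-associated miR-17-92 cluster with its paralogs was at -0.80 (0.05th). From day 0 to day 24 striated muscle markers stood 1.81 higher (99.9th percentile) and the miR-101 family 2.19 higher (98.4th). Of the muscle markers miR-206-3p, the most abundant, went the other way, to 0.147 of its TMM-scaled day 0 level. Over the same whole course the miR-29 family stood only 0.44 higher (86.1st percentile), after -0.47 (10.9th) from day 0 to day 6, and the miR-17-92 list was at -0.59 (1.65th). The steps printed for each list were chosen after their values were seen, compare single libraries and carry no test. Random lists were drawn member by member, while members of a family or cluster can move together (estimated correlation with day 0.902 for miR-15/16). The percentiles therefore overstate how unusual a list is. The miR-15/16 and miR-322 lists also share miR-322-5p. The miR-101 list has 3 measured members. Of these, miR-101b-3p did not rise from day 6 (3000 RPM) to day 24 (2589 RPM), and miR-101c may share reads with miR-101a-3p. The median of that list may therefore stand for 1 signal.

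With the day trend on summed counts per mature miRNA, none of the 18 lists tested passed in camera (lowest adjusted p = 0.125) or with an estimated correlation. fry called 1, the miR-23/27/24 clusters, upward (adjusted p = 0.0484), with positive slopes in 7 of 7 members and a median of 0.54. Without day 0, camera called the miR-29 family upward (0.0176) and the miR-17-92 cluster and paralogs downward (0.0212). Over all days their adjusted p was 0.79 and 0.749 with an estimated correlation. The miR-101 family had 1 of 3 measured members rising over all miRNAs and 2 adjusted over the list alone (median 2.19). These 2 were miR-101a-3p and miR-101c, which may share reads, while miR-101b-3p had -0.05. Among miRNAs reported to promote osteoblast differentiation, miR-210-3p rose and miR-196a-5p fell, and 7 of 9 did not pass (median 0.44), among them miR-29a-3p (0.44) and miR-218-5p (1.33). Adjusted over the list alone, 1 rose and 2 fell. None of 10 miRNAs reported to restrain differentiation passed (median 0.03), with miR-125b-5p at -0.58, miR-34c-5p at -0.30 and miR-214-3p at -0.27.

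Among the families, no member passed over all miRNAs in the miR-29 family (median 0.65 over 6), the miR-17-92 cluster and paralogs (-0.61 over 9, 3 falling when adjusted over the list alone), the let-7 family (0.19 over 10), the miR-34 family (-0.30 over 5), the miR-30 family (-0.23 over 7, 2 falling over the list alone) and the miR-15/16 family (0.40 over 6, 2 rising over the list alone). The same held for the miR-322 and miR-503 cluster (0.34 over 8), miR-199 and miR-214 (0.07 over 6), miR-143 and miR-145 (0.07 over 4), the miR-23/27/24 clusters and the miR-183, miR-96 and miR-182 cluster (-0.21 over 3, but 0.13 with library totals). In the miR-17-92 list miR-92a-3p had -1.80, miR-20a-5p -1.45 and miR-25-3p -0.08. let-7c-5p had 0.98, let-7i-5p 0.40 and let-7f-5p 0.07. Of the Hox cluster miRNAs, miR-196a-5p fell (-2.77 ± 0.37), and miR-615-3p (-1.89), miR-10a-5p (-0.63) and miR-196b-5p (0.38) did not pass; 2 of 5 fell when adjusted over the list alone. With library totals no list member passed on summed counts, and medians lay higher, at 0.49 for let-7, -0.07 for miR-30, 0.34 for miR-199 and miR-214, 0.37 for miR-143 and miR-145 and 0.24 for the miRNAs reported to restrain differentiation.

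Of the markers of other cell types, few passed with day on summed counts. miR-146a-5p rose (3.22 ± 0.59) among 3 measured blood cell miRNAs, of which miR-155-5p had -5.54 (adjusted p = 0.0502) and miR-486-5p 0.41; over the list alone 1 rose and 1 fell. No cartilage miRNA of 4 passed (median 0.33), with miR-140-3p at 0.00. Of 4 striated muscle miRNAs none passed (median 1.45), with miR-499-5p at 3.55, miR-1a-3p at 1.68 and miR-206-3p at -2.56. Over the muscle list alone 2 rose and 1 fell, and with DESeq2 size factors or upper quartile factors 1 rose over all miRNAs. With upper quartile factors 1 blood cell miRNA also fell. miR-126-3p of endothelium (-1.06), miR-128-3p (-1.05) and miR-9-5p (1.37) of the nervous system, miR-205-5p of epithelium (0.86) and miR-379-5p of the Dlk1-Dio3 cluster (-1.30) did not pass. Over the list alone, 1 nervous system miRNA rose and 1 fell. Median and mean differed in sign for the blood cell list (0.41 and -0.64), for miR-143 and miR-145 (0.07 and -0.01) and for the miRNAs reported to restrain differentiation (0.03 and -0.03), each with an upward camera direction.

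How the cultured line differs from bone tissue was asked by setting the 3 calvaria libraries against the 5 MC3T3 libraries. The largest differences belonged to the imprinted Dlk1-Dio3 cluster, a run of maternally expressed miRNAs. miR-127-3p held 11708 ± 3722 RPM in calvaria (SD, n = 3) and 1.15 ± 1.56 in MC3T3 (n = 5). Of 47 listed members 45 passed the count filter, nearly all of them through their calvaria counts, and all 45 were higher in calvaria. In the other direction the Hox-embedded miR-196b-5p was at 0.447 ± 0.425 RPM in calvaria and 93.8 ± 41.8 in MC3T3, miR-31-5p at 21.2 ± 7.31 and 2888 ± 1076, miR-10a-5p at 127 ± 42.0 and 6075 ± 585, and miR-34c-5p, a target of p53, at 348 ± 38.9 and 10792 ± 2443.

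Of 551 entries tested, 180 were higher and 186 lower in calvaria at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The split moved with the scaling, to 216 and 128 with DESeq2 size factors, 143 and 251 with upper quartile factors, and 179 and 137 with library totals. The DESeq2 Wald test, which changes both the scaling and the test, gave 222 and 109. Summed per mature miRNA, 167 of 471 were higher and 135 lower. The median log2 difference of all mature miRNAs was 0.06 with TMM, 0.23 with DESeq2 size factors, 0.25 with library totals and -0.37 with upper quartile factors, and small differences should be read against that shift. Without calvaria 1, 2 or 3 in turn, 97 to 102 were higher and 95 to 113 lower. With the filter in 2 libraries, a setting added after the data were seen, these became 184 and 123, 181 and 117, and 178 and 176, so lower calls stayed fewer without calvaria 1 or 2. Without the day 0 library, 202 were higher and 187 lower.

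miR-101a-3p did not differ detectably from MC3T3 over all days (log2 -0.25 ± 0.45, adjusted p = 0.643, edgeR quasi-likelihood test). It was lower in calvaria than in MC3T3 at days 17 and 24 (-0.99, adjusted p = 0.00146; -0.70, 0.0105 with the filter in 2 libraries), and against days 0 and 6 the difference was 0.68 (0.126). miR-101b-3p was lower by a small margin (-0.50 ± 0.16, adjusted p = 0.0219), a call lost with DESeq2 size factors (0.325), the DESeq2 Wald test (0.226), library totals (0.194), limma (0.167 and 0.179) and without calvaria 1 (0.295), 2 (0.394) or 3 (0.224). With the filter in 2 libraries it was kept without calvaria 3 (-0.59, 0.0333) and lost without calvaria 1 (0.189) or 2 (0.256) and against days 0 and 6 (0.107). miR-101c did not differ over all days (-0.22 ± 0.47, adjusted p = 0.686), but was lower than at days 17 and 24 (-1.10, 0.00422) and not detectably different from days 0 and 6 (0.72, 0.107). With the filter in 2 libraries, added after the data were seen, it was higher than at days 0 and 6 (0.89, 0.0317) and lower than at days 17 and 24 (-0.82, 0.0167). On summed counts, 1 of 3 measured members of the miR-101 family was lower (median -0.32, adjusted over the list alone 1), and none with DESeq2 size factors or library totals.

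The Dlk1-Dio3 members tested spanned 172 kb of chromosome 12 (109571990 to 109743795, plus strand, 38 precursors). Together they held 45480 ± 8330 RPM in calvaria and 16.6 ± 8.01 in MC3T3, or 211391 and 274 counts. All 45 were higher (45 adjusted over the list alone), with a median log2 difference of 10.01, or 9.52 with the 16 members that had 0 MC3T3 counts set at their bound. Another 14 had 1 to 3 MC3T3 counts. The pooled ratio of RPM was 10900 (95% interval 6950 to 18000) for miR-127-3p, 2520 (2020 to 3200) for miR-379-5p and 2130 (1550 to 3030) for miR-411-5p. From 2 MC3T3 counts miR-434-3p had 11700 (3250 to 96900), and by its calvaria mean against the 3-count limit miR-337-5p was at least 2521-fold and miR-136-5p at least 1667-fold higher. miR-434-5p, miR-127-5p, miR-341-3p, miR-370-3p and miR-431-5p were the other members among the 10 largest differences. Camera gave the list an adjusted p of 5.17e-22, but adjusted p = 0.316 with an estimated correlation. Of the 47 listed members, only 1 passed the filter of the day trend in MC3T3. The filter therefore largely fixed the direction of the others, and the share of members higher and the camera values carry that selection. It did not fix the size of the differences. Mir127 is at chromosome 12, 109592846 to 109592915, antisense to an exon of Rtl1.

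**Figure D3:**
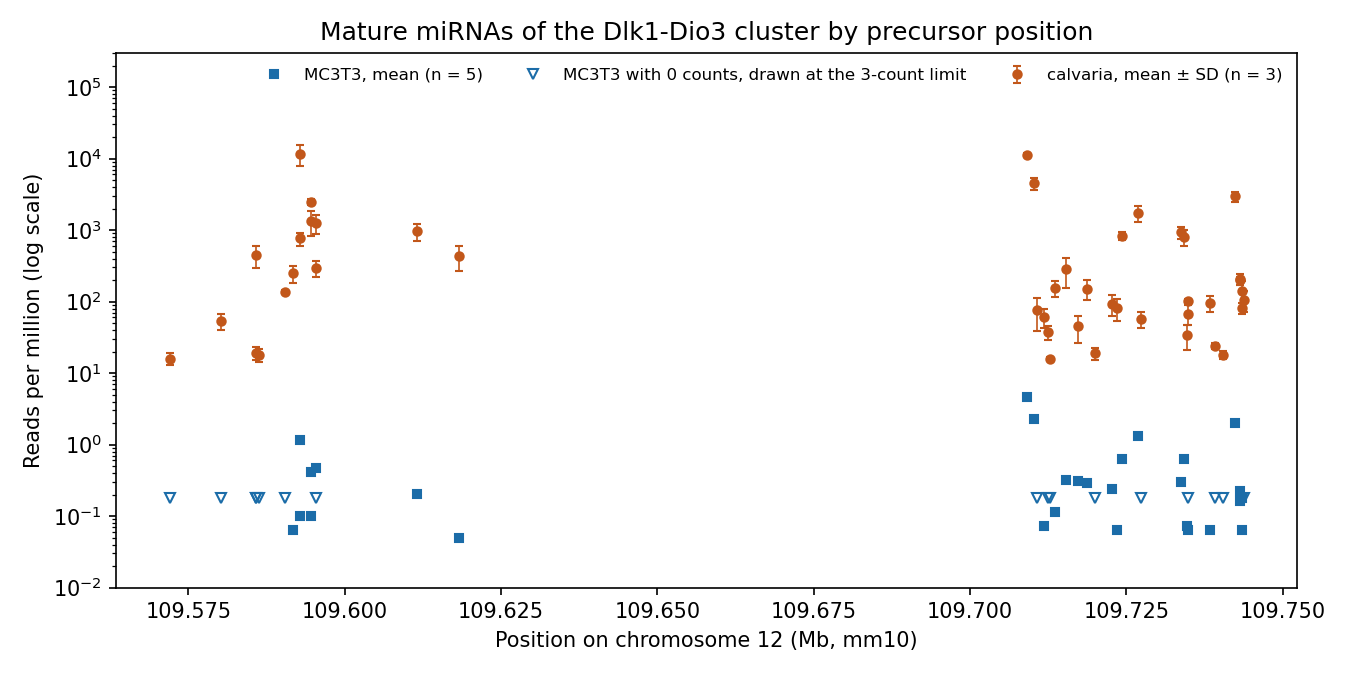
Mean RPM (log axis) of 45 Dlk1-Dio3 miRNAs against the position of their precursors on chromosome 12 (Mb, mm10), in calvaria (circles, mean ± SD, n = 3) and MC3T3 (squares, mean, n = 5; open triangles mark 0 counts at the 3-count limit). Calvaria levels run from 15.9 to 11700 RPM, and no MC3T3 mean passes 4.60 RPM.

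The list values that follow are from summed counts. The miR-34 family, induced by p53, was lower in all 5 measured members (median -5.14, 5 adjusted over the list alone), among them miR-34c-5p (-5.14 ± 0.24), miR-34b-5p (-5.30 ± 0.55) and miR-34a-5p (-2.44 ± 0.25). Camera gave an adjusted p of 0.00149, and adjusted p = 0.316 with an estimated correlation. The miR-29 family was lower in 5 of 6 members (5 over the list alone, median -2.16), with miR-29a-3p at 646.5 RPM in calvaria and 3284 in MC3T3 (-2.57 ± 0.30). Its miR-29b-3p (-2.06 ± 0.43) and miR-29c-3p (-2.12 ± 0.45) were lower too. Camera gave an adjusted p of 0.0499 (adjusted p = 0.538 with an estimated correlation), lost without day 17 (0.0561), calvaria 2 (0.0741) or calvaria 3 (0.0563). The 10 largest decreases were completed by miR-31-3p (-6.62), miR-615-3p (-6.19), the passenger arms of miR-34b and miR-34c, and miR-708-5p (-3.93), which lies in an intron of Tenm4.

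Of the 5 Hox cluster miRNAs, 4 were lower and 1 higher (the same adjusted over the list alone). miR-10a-5p (-5.83), miR-196a-5p (-7.51), miR-196b-5p (-7.71) and miR-615-3p (-6.23) were lower, while miR-10b-5p of the HoxD region was at 2145 RPM in calvaria and 8.94 in MC3T3 (7.67 ± 0.37). Camera did not call the list (adjusted p = 0.0814). miR-340-5p, hosted by Rnf130, was the only one of the 10 largest increases outside the Dlk1-Dio3 cluster (2756 ± 412 RPM against 0.341 ± 0.400).

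Among miRNAs reported to promote osteoblast differentiation, 5 of 9 were lower and none higher (5 over the list alone, median -1.89): the 3 guide arms of the miR-29 family, miR-15b-5p (-1.89) and miR-196a-5p. miR-218-5p (-0.32) and miR-20a-5p (0.32) did not pass, and camera gave an adjusted p of 0.0859. Of those reported to restrain it, 3 of 10 were higher and 3 lower (the same over the list alone, median -0.34, camera adjusted p = 0.38), and 3 and 6 with upper quartile factors (median -0.78). miR-23a-3p (1.91 ± 0.25), miR-133a-3p (2.99 ± 0.38) and miR-217-5p were higher, the last at 48.0 RPM against 0 MC3T3 counts, or at least 271.6-fold. miR-31-5p, miR-34c-5p and miR-125b-5p (-1.29 ± 0.21) were lower.

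The miR-143 and miR-145 miRNAs were lower in 4 of 4 (4 over the list alone, median -1.15, camera adjusted p = 0.0649), with miR-143-3p at -1.10, miR-145a-5p at -1.28, miR-145a-3p at -1.21 and miR-143-5p at -0.95. The miR-322 and miR-503 cluster was higher in 8 of 9 (9 over the list alone, median 1.47), with miR-322-3p at 0.86, miR-450a-5p at 0.97 and miR-503-5p at 1.94, while miR-351-5p (0.49) did not pass. Camera gave it an adjusted p of 0.151 (adjusted p = 0.799 with an estimated correlation). It called the list without calvaria 1 (0.00441), 2 (0.00880) or 3 (0.00761), settings in which the filter also removes miRNAs seen in calvaria alone from the lists and the background. In the miR-17-92 list miR-19a-3p (0.83) and miR-19b-3p (0.81) of 9 were higher (2 over the list alone, median 0.57, adjusted p = 0.629), but none with upper quartile factors, where 1 was lower; miR-92a-3p (0.72), miR-20a-5p (0.32) and miR-25-3p (0.35) did not pass.

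Several families had few passing members, and the sign or size of their medians depended on the scaling. The let-7 family had let-7c-5p (-1.30) and let-7b-5p (-1.26) lower of 9 (2 over the list alone), with a median of -0.04 that was 0.13 with DESeq2 size factors and -0.49 with upper quartile factors, where 5 were lower (camera adjusted p = 0.488); let-7i-5p had 0.12 and let-7f-5p -0.04. The miR-30 family had miR-30b-5p higher (1.60) and miR-30a-5p (-1.38) and miR-30a-3p (-1.28) lower of 7, the same over the list alone, and miR-30d-5p (-0.18) and miR-30e-5p (-0.10) did not pass. Its median of -0.18 was 0.05 with library totals and -0.63 with upper quartile factors, where 1 was higher and 5 lower (adjusted p = 0.606). In the miR-15/16 family miR-322-5p was higher (1.2) and miR-15b-5p lower of 6, the same over the list alone (adjusted p = 0.750), and miR-16-5p (0.07) and miR-195a-5p (-1.37) did not pass.

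miR-199a-3p and miR-199b-3p (0.51 each), which have the same mature sequence and are 1 signal divided between 2 names, were higher in the miR-199 and miR-214 list of 6. None passed when adjusted over the list alone, and with upper quartile factors none was higher and 1 lower, with the median of 0.27 at -0.18 (adjusted p = 0.933); miR-199a-5p had 0.01. In the miR-23/27/24 clusters miR-23a-3p was higher and miR-27b-3p lower (-0.65) of 7, with 1 and 0 over the list alone. None was lower with DESeq2 size factors or library totals and 3 were with upper quartile factors (median -0.41); miR-24-3p had 0.02 and miR-27a-3p -0.51. The median was 0.02 and the mean 0.16 with a downward camera direction (adjusted p = 0.873). In the miR-183, miR-96 and miR-182 cluster miR-96-5p (-1.12, adjusted p = 0.0498) was lower of 3, with none over the list alone and none with DESeq2 size factors or library totals (camera adjusted p = 0.488); miR-182-5p had -0.43 and miR-183-5p -0.67.

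**Figure D4:**
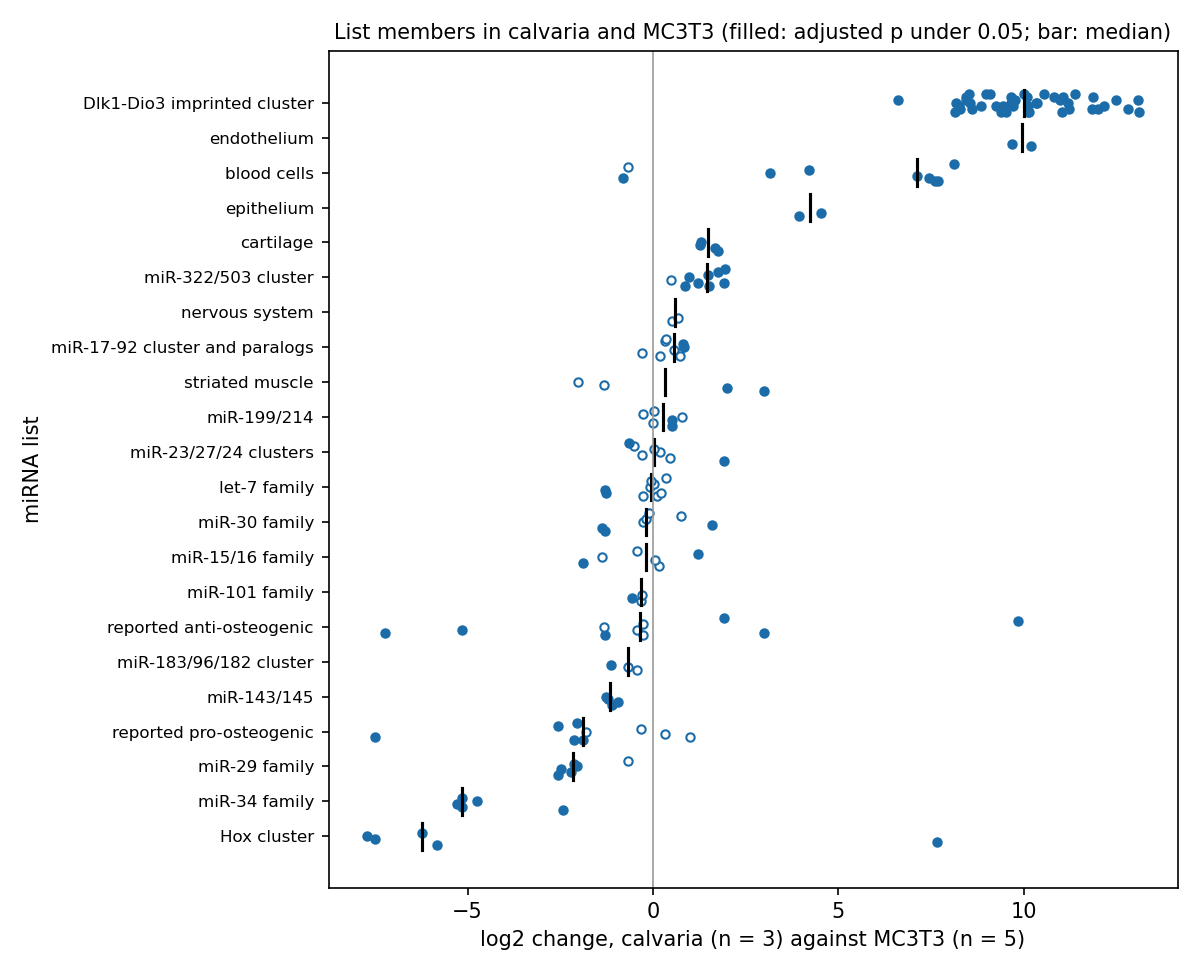
Log2 difference of calvaria (n = 3) from MC3T3 (n = 5) on the horizontal axis for each measured member of the 22 lists (rows), with filled points past an adjusted p of 0.05 and bars at the list medians. The Dlk1-Dio3 median lies at 10.01 and the Hox cluster median at -6.23, with miR-10b-5p on the other side at 7.67; medians of lists near 0 change sign with the scaling.

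Endothelial and cartilage markers and most of the measured blood cell markers were higher in calvaria. Both endothelial arms were, miR-126-3p with 12320 RPM against 9.17 (log2 10.21 ± 0.43) and miR-126-5p with 1049 against 1.07 (9.68 ± 0.29). All 4 cartilage miRNAs were (4 over the list alone, median 1.49), with miR-140-3p at 73350 RPM against 18890 (1.76 ± 0.23), miR-140-5p at 1.68 and miR-455-5p at 1.29. Camera did not call that list (adjusted p = 0.312, and adjusted p = 0.799 with an estimated correlation), except without calvaria 3 (0.0148), where the filter also removes miRNAs seen in calvaria alone from the background. Of 9 blood cell miRNAs measured of 12 listed, 7 were higher and 1, miR-486-5p (-0.80), lower (the same over the list alone), though not with DESeq2 size factors or library totals. miR-451a of erythroid cells had 124 RPM against 0.437, miR-146a-5p 172 against 17.3, and miR-223-3p of myeloid cells 33.9 against 1 MC3T3 count, a pooled ratio of 560 (98.9 to 22300). In MC3T3 alone, 3 of the 12 listed passed the filter of the day trend. The other measured ones were tested through their calvaria counts, which largely fixed their direction. Camera gave the list an adjusted p of 0.0499 (adjusted p = 0.408 with an estimated correlation). That call was lost without day 6 (0.0561), day 10 (0.0517), day 17 (0.0561), calvaria 1 (0.3), calvaria 2 (0.303) or calvaria 3 (0.381). A minimum of 100 counts removed it as well (0.587).

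Of the 7 epithelial miRNAs listed, 2 passed the count filter and were higher, miR-203-3p at 54.9 RPM against 2.11 (4.53 ± 0.64) and miR-200b-3p at 12.6 against 0.694 (3.95 ± 0.49). miR-205-5p, left untested by the filter, stood the other way, at 1.44 RPM against 2.38. Of 4 striated muscle miRNAs miR-1a-3p (2.00 ± 0.39) and miR-133a-3p were higher, and miR-206-3p (-1.33) did not pass (camera adjusted p = 0.879); the median of 0.33 was -0.09 with upper quartile factors, where 1 was lower. miR-128-3p (0.52) and miR-9-5p (0.68) of the nervous system did not pass. Adjusted over the list alone, 2 of 2 endothelial, 2 of 2 epithelial, 2 of 4 muscle and 0 of 2 nervous system miRNAs were higher. Summed over each list, calvaria held 13370 ± 6090 RPM of endothelial and 573 ± 115 RPM of blood cell miRNAs beside the 45480 RPM of the Dlk1-Dio3 cluster. Between the calvaria libraries the endothelial sum ranged from 9028 to 20320 RPM and the cartilage sum from 61230 to 111600 RPM.

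Across the lists in calvaria against MC3T3, camera called 4 of 19, none with an estimated correlation, and 7 with library totals; fry, which does not compare a list with other miRNAs, called 12. Passing members also moved with upper quartile factors in the miR-29 family (6 lower), the miR-322 and miR-503 cluster (6 higher), the cartilage list (3 higher) and the miR-183, miR-96 and miR-182 cluster (2 lower). With DESeq2 size factors 4 were higher in the miR-17-92 list and 1 in the nervous system list.

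Whether miRNAs that moved with day also differed between bone and the line was asked across 377 miRNAs in a joint fit. The day slope and the calvaria difference had a Spearman rho of 0.143 and a covariance of 0.110, beside -0.004 ± 0.051 and -0.0013 ± 0.014 in 50 simulations with no effect. With the slope from 3 MC3T3 days and the difference from the other 2, the values were 0.0857 and 0.0315, with no simulated values beside them. The simulations held no difference between materials or days. Real differences were large, and miRNAs of a cluster covaried (estimated correlation 0.837 for miR-322 and miR-503 with day). The simulated spread therefore cannot show whether these values exceed chance. Of 14 rising miRNAs, 2 were higher and 6 lower in calvaria, where independent lists would share 3.31 and 5.27. Of 13 falling miRNAs, 4 were higher and 5 lower, against 3.07 and 4.90. These rising and falling miRNAs were counted among the 377 of this comparison. They are not the 6 rising and 8 falling entries of the main day trend. The mean rank correlation of each day with the 3 calvaria libraries was 0.501 at day 0 and 0.520 to 0.527 on the later days.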

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

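The depth test for the day 0 library, like the regrouping of libraries and the reordering of days, was set before the results were seen; the tests of the Dlk1-Dio3 cluster, of day 0 as a single culture and of miR-101c were chosen after.

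Over the 5 MC3T3 libraries, 34 sets of values were searched for 1 library lying far from the rest, meaning a gap of more than 0.71 of the whole range, and 7 were found. Such a rule finds about 1 in 20 groups by chance where values are roughly normal. Near 0 that rate does not hold, since a single count against 0 elsewhere always passes. Some of these cases therefore need no cause. At day 0 the 10 most abundant miRNAs took 76.6% of counts (61.8% to 62.4% on the other days) and miR-21a-5p took 45.6% (11.2% to 20.1%). Also at day 0, miR-30c-2-3p had 335 RPM (102 to 166) and miR-615-3p 164 RPM (51.4 to 79.5). The remaining cases rest on few counts: miR-370-3p with 0.248 RPM at day 0 (0 elsewhere), miR-101b-5p with 0.317 RPM at day 6 (0 elsewhere) and miR-127-3p with 3.8 RPM at day 6 (0 to 0.992).

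The Dlk1-Dio3 cluster was near absent from MC3T3 and abundant in calvaria. Over 4 scalings the lowest median log2 difference was 9.673, so the choice among them did not make the difference. They moved the median of all mature miRNAs only between -0.37 and 0.25, so this test could hardly have come out otherwise. Blood cell miRNAs were scarce beside the cluster, at most 1.91% of its RPM. How much of the cluster a blood cell carries is not given in the sources used here, so this ratio alone does not exclude blood cells. Endothelial cells stayed open too. miR-126 arms reached at most 55.9% of the cluster, in the library with the most miR-126 (20320 RPM) and the least of the cluster (36330 RPM). With 3 libraries this does not settle how the 2 vary together. The cluster miRNAs carried per endothelial cell are not given in the sources used here. A loss of expression in the cell line or a cluster active in other bone cells could fit as well, and neither was tested.

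The day 0 library stood apart from the later days. Depth left beside miR-21a-5p was argued against: after all MC3T3 libraries were thinned to equal depth without that miRNA, the lowest gap in rank correlation over 20 draws was still 0.0208. Day 0 may differ because its cells were undifferentiated, per its title. Its column name also lacks the "veh" mark of the later days. A difference of that culture or library other than its day could not be separated from this with 1 library of day 0.

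miR-101c followed miR-101a-3p over the libraries. Its ratio to miR-101a-3p stayed within a 1.76-fold range (0.431% to 0.757%), against a 4.6-fold range of its ratio to miR-101b-3p. The chi-square p for a constant ratio to miR-101a-3p over 8 libraries was 0.0199, from 28 to 152 miR-101c counts, and 2.49e-22 for miR-101b-3p. Reads shared between miR-101c and miR-101a-3p could give such a course, and so could a common regulation. The test left both open. A read within the run of 19 bases shared by the Mir101a and Mir101c precursors cannot be assigned by its sequence. The miR-101c values may therefore not be a separate signal.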

How the results depend on the processing

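The settings named as having the filter in 2 libraries were added after the results were seen; all others were set before. Causes were not tested unless stated. With day, main counts were 6 rising and 8 falling. They were 20 and 14 with the DESeq2 Wald test, 14 and 20 with no count filter, 2 and 2 with a filter of 100 counts, 47 and 56 on log2(day + 1), 15 and 18 on the rank of the day, and 11 and 2 on deposited RPM with limma and a pseudocount of 10. Fewer fell with library totals (5), a limma pseudocount of 1 (2) and summed counts (5). Leaving out single libraries, rising ranged from 0 (without day 6) to 35 (without day 0) and falling from 2 (without day 17) to 40 (without day 0). The miR-101a-3p day change of 2.26 missed the threshold in the main fit and with the other scalings. It passed with the DESeq2 Wald test (2.261), a limma pseudocount of 10 (2.53) and no count filter (2.221). Other passes came on log2(day + 1) (2.446), on the rank of the day (2.335) and with all 8 libraries sharing the spread (2.23). With libraries left out, the change ranged from 1.409 (without day 0) to 3.202 (without day 24). Day lists called went from 0 to 1 with fry, and from 0 (without day 6) to 2 (without day 0). For calvaria, main counts were 180 higher and 186 lower. Lower ones were 109 with the DESeq2 Wald test. Against days 0 and 6 they were 101 of 436 entries tested, but 172 of 563 with the filter in 2 libraries. A filter of 100 counts left 85 higher and 87 lower, of 280 entries tested. Without calvaria 1 or 2 and with the filter in 2 libraries, 123 and 117 were lower. Leaving out single libraries, higher ranged from 97 (without calvaria 2) to 202 (without day 0) and lower from 95 (without calvaria 3) to 187 (without day 0). miR-101a-3p, at -0.25, became lower in calvaria against days 17 and 24 (-0.9885, or -0.7027 with the filter in 2 libraries), and left-out libraries moved it between -0.4545 and 0.0477. miR-101c reversed to 0.8898 against days 0 and 6 with the filter in 2 libraries, while with the filter in 3 it was 0.7199 and did not pass; its day course places those days lowest. Calvaria lists called were 4 in the main setting, 7 with library totals, 0 with an estimated correlation, 12 with fry, 2 with a filter of 100 counts, and from 2 (without day 17) to 4 (without day 0) with libraries left out.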

Other observations

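Of the miRNAs in these paragraphs, those outside the lists were chosen after their values were seen, and no test was chosen for them. Outside the lists, the Igf2 intron miRNAs miR-483-3p (311 ± 153 RPM in calvaria, 0.238 in MC3T3, log2 9.93) and miR-483-5p (8.65) were higher in calvaria, as were miR-224-5p (6.91), miR-181c-5p (5.78) and miR-181d-5p (5.08). Lower were miR-193b-3p (-2.78), miR-365-3p (-2.68), miR-222-3p (-2.32), miR-221-3p (-2.15), miR-21a-5p (-1.89) and miR-22-3p (-1.67). The entries miR-6243 (21950 ± 2560 RPM in calvaria, 583 ± 263 in MC3T3) and miR-5109 (15400 ± 2000 and 129 ± 41.7) have no annotated precursor gene. Whether they are miRNAs or fragments of ribosomal RNA was not tested, so these values are not read as miRNA levels; the same holds for miR-6240 and miR-5115.

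Whether any grouping of the libraries gives as many calls as tissue against cell line was tested by splitting the 8 libraries into 3 and 5 in all 56 ways. Only 1 split, the real one, gave as many entries at an adjusted p under 0.05 (366), and the highest other gave 0. Every other split mixed calvaria and MC3T3 libraries in at least 1 group, which widens the spread the test uses. Rank correlations were 0.488 to 0.54 between materials, and at least 0.956 among MC3T3 and 0.974 among calvaria libraries. The splits therefore only restate that the materials differ. They cannot tell tissue from any other difference between these sets of libraries. For the day trend, 4 of 100 orders of the 5 days, the real one among them, gave at least 14 entries. The highest count, 47, came from the days exactly reversed, which keeps the sequence and changes the gaps.

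The series title names miR-101a, and its guide arm went from 1015 to 7174 RPM while miR-101b-3p stayed within 1931 to 3008 RPM. The call depended on the model. On the linear scale the log2 change of 2.26 did not pass in the edgeR quasi-likelihood test, but it did with the DESeq2 Wald test (2.261), with no count filter (2.221), with all 8 libraries sharing the spread (2.23) and without day 0, 10 or 24. It also passed on log2(day + 1) (2.446), a scale that the 3-day difference between column names and titles would change. The change missed the threshold with DESeq2 size factors, library totals or upper quartile factors, and with a limma pseudocount of 1. The same held with a minimum of 100 counts, with summed counts, and without day 6 or 17. Each day was a single pooled library, so spread between cultures and a curved course could not be told apart.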
